A study of Mus musculus with 7 samples.

How the data were processed

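Chromatin immunoprecipitation sequencing measured IRF4 binding in WT Treg cells (3 samples) and in p65KO Treg cells (2 samples), and p65 binding in WT Treg cells (2 samples), per the labels. Groups were taken from the sample titles. Per the labels' protocols, cells for IRF4 received anti-CD3 plus anti-CD28 over 48 h and cells for p65 PMA plus ionomycin over 30 min, and libraries were sequenced on an Illumina HiSeq instrument. Per the labels, the antibodies were the Santa Cruz anti-IRF4 M-17 and anti-p65 C-20.

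The authors deposited 3 lists of peak summits, 1 per group, and the labels of every sample of a group name the same list. MACS2 2.1.0, Subread and featureCounts are named in the submitters' processing notes, with the genome build mm9; the settings of each are not given in the sources used here. Each line holds the 1 bp summit of a peak and the authors' deposited score, a −log10 significance value of that peak. Whether it is −log10 of the p-value or of the q-value is not given in the sources used here; every deposited value exceeds −log10 of the q cut-off. The cut-offs, q = 1e-06 for IRF4 and q = 0.05 for p65, are those in the names of the deposited lists, and every peak name carries the words No-Input, so peaks were called without an input library per the peak names. Without one, sequence that attracts reads whatever the antibody is not subtracted. How replicates were combined is not given in the sources used here, and nothing says whether they came from separate animals. The scores are the authors' own and were used to describe, rank and stratify summits within a list, and for Spearman and Pearson correlations at matched positions.

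Summit positions were converted to 1-based coordinates. A summit counted as matched when the nearest summit of the other list lay within 200 bp, and IRF4 pairs of the 2 genotypes were mutual nearest neighbours. Chance matching was measured by shifting all summits 5, 10, 20 and 50 kb up and down, giving 8 shifts. Shares have 95% Wilson intervals. Odds ratios come from Fisher's exact test or, within strata of score, from the exact Cochran-Mantel-Haenszel test. The strata were deciles of the WT IRF4 score unless stated otherwise. Differences in median score and correlations were tested with 100000 permutations, whose smallest p is 1e-05, and intervals of rho with 2000 bootstrap resamples. All tests were two-sided. Benjamini-Hochberg adjustment covered the 8 planned tests together and the 12 correlations together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9 were used.

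Summits, not samples, are the units of these tests. Replicates are pooled in the lists, so the intervals and p-values cover counting error over summits and not the variation between animals or libraries. Read depth per sample is unknown, because summit lists hold no read counts. The WT and p65KO IRF4 lists rest on different numbers of samples, and the p65 list on a looser q cut-off.

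The matching distance, tests, strata, cluster definition, alternatives and the rule for named summits were chosen before the data were examined. The rule took the 10 highest summits of each list, the 10 highest WT IRF4 summits with p65 that had no p65KO summit within 1 kb, the 10 highest that had both, the 5 clusters with most WT IRF4 summits, and the 5 highest p65KO IRF4 summits with no WT summit within 1 kb. Summits named outside this rule are marked in the text as chosen after their values were seen, and so are the 3 WT IRF4 summits without p65, the p65KO summits with p65 and no WT partner, and the dense p65 regions. The separation of unplaced sequence (contigs named random or Un, and the mitochondrial genome) and of dense p65 regions (at least 3 p65 summits no more than 50 kb apart) was added after the lists were seen. The dense regions are defined from the p65 list itself.

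Alternatives were matching within 100 bp, 500 bp and 1 kb, summits above each list's median score, IRF4 lists of equal length, autosomes only, 1 summit per 500 bp, other numbers of score strata (4 and 20), and clusters joined at 5 and 25 kb. Added after the lists were seen were leaving out unplaced sequence and dense regions, p65 within 10 kb in place of 200 bp, both together, and the upstream in place of the downstream shift. No genome or annotation of the mm9 build was used here, and the gene table at hand describes another build, GRCm38.p6, so none of its coordinates were used. Gene assignment, genomic location, motif searches and the tests of gene lists, all planned, were therefore not run.

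The matching and stratified tests were tested on simulated data of the size of these lists. Simulated summits were placed uniformly along the chromosomes, and p65 partners were drawn at random among the WT IRF4 summits. The crowding of p65 summits in unplaced sequence and dense regions was not simulated, so the recovery given next does not cover it. With 28% of p65 summits planted on WT IRF4 summits, 28.1% were recovered. A planted retention odds ratio of 0.5 was recovered with a median of 0.498 in 40 simulations, all 40 with p below the 0.05 level, and a planted odds ratio of 1 gave 0.974, with 2 of 40 below it.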

Results

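The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from mouse regulatory T (Treg) cells of the spleen, on a C57BL/6 background. IRF4 is a transcription factor needed by activated, effector Treg cells, and RelA (p65) is a DNA-binding and activating subunit of the canonical NF-κB pathway. IRF4 was precipitated from wild-type (WT) cells in 3 samples and from RelA-deficient (p65KO) cells in 2 samples, after 48 h of anti-CD3 and anti-CD28 stimulation. RelA was precipitated from WT cells in 2 samples, after 30 min of PMA and ionomycin. The series' stated purpose was to find the genes that each factor targets in these cells. Each group came as 1 list of peak summits without values per replicate, so no value below has a replicate error. Positions are mm9 coordinates, 1-based, and gene names and gene features were not assigned.

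The WT IRF4 list held 5630 summits and the p65KO IRF4 list 4312. The p65 list held 797. The authors' peak score, on a −log10 scale, had a median of 26.3 (interquartile range 18.1 to 43.7) in WT IRF4, 27.3 (18.8 to 45.0) in p65KO IRF4 and 9.61 (6.17 to 17.7) in p65. Read depth is unknown from summit lists, and the lists were cut at different q-values, 1e-06 for IRF4 and 0.05 for p65. A difference in list length therefore cannot be read as a difference in binding.

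A larger share of p65 than of IRF4 summits lay on unplaced contigs. Of the p65 list, 192 summits (24.1%) lay on unplaced contigs or the mitochondrial genome, against 97 (1.72%) of the WT IRF4 list, an odds ratio of 18.1 (95% interval 13.9 to 23.7, two-sided Fisher's exact test, p = 5.8e-110). Fisher's test treats these summits as independent although many p65 summits there lie close together, so its interval and p-value do not allow for crowding. The p65 list also had the looser q cut-off. On unplaced Y sequence there were 50 p65 summits, 4 WT IRF4 summits and no p65KO IRF4 summit. A further 298 p65 summits (37.4%) crowded into 39 regions of the placed chromosomes, each with at least 3 p65 summits no more than 50 kb apart, called dense p65 regions from here on and defined by the p65 list itself. Chromosome 5 from 14900181 to 15062141 held 39 p65, 20 WT IRF4 and 6 p65KO IRF4 summits. Chromosome 8 from 19854737 to 20032951 held 38, 9 and 9. The dense regions on chromosome 9 from 3000455 to 3038150 and on chromosome 11 from 3000344 to 3098951 lay at the start of their chromosomes' sequence, with 15 and 19 p65 summits. The remaining 307 p65 summits (38.5%) were spread over the placed chromosomes, where 5433 (96.5%) of the WT and 4212 (97.7%) of the p65KO IRF4 summits also lay. This division was made after the lists were seen.

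**Figure D1:**
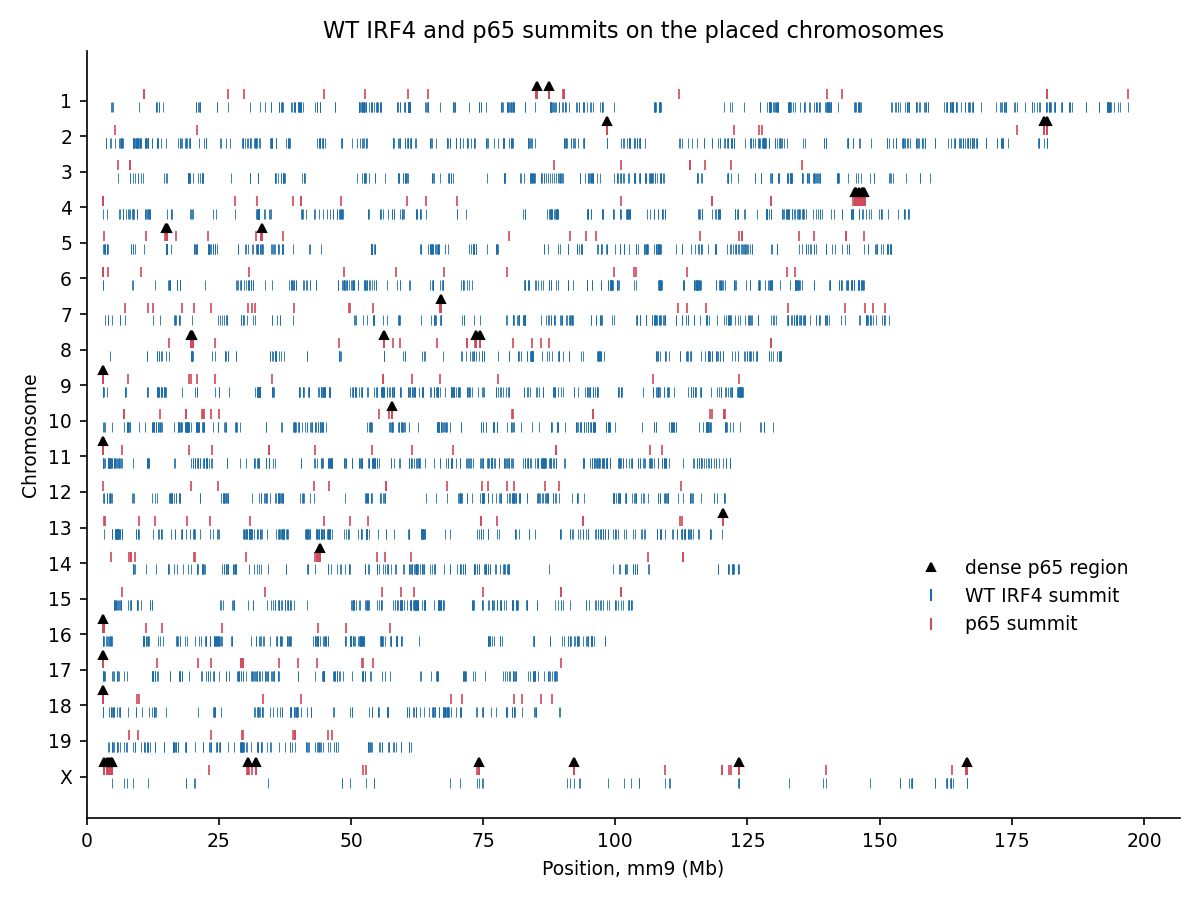
Positions of WT IRF4 summits (blue ticks, lower line of each chromosome) and p65 summits (red ticks, upper line) along the placed mm9 chromosomes, in Mb, with dense p65 regions as black triangles. IRF4 summits are spread over every chromosome drawn, while 298 of the 797 p65 summits fall in the 39 marked regions.

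The first comparison asked how far the map of IRF4 binding changed without RelA. The strongest IRF4 sites of WT cells were also called in p65KO cells: each of the 10 highest WT summits had a p65KO summit within 200 bp, and each of the 10 highest p65KO summits a WT summit. In each list 6 of these 10 also had a p65 summit within 200 bp, and all peaks were called without an input library. The highest in both lists was chromosome 9 at 35112991, with scores of 319 in WT and 350.7 in p65KO. It was followed in both lists by chromosome 16 at 11144200 (305 and 327) and chromosome 3 at 5860628 (279 and 296). The other WT summits of the top 10 were chr1_random at 272714, chromosome 11 at 61458225, chromosome 16 at 57391617, chromosome 13 at 113077514, chromosome 9 at 95052344, chromosome 5 at 147072755 and chromosome 18 at 65638959. The p65KO top 10 shared 6 positions with the whole WT top 10 and added chromosome 8 at 48026862, chromosome 6 at 47571265, chromosome 10 at 44164412 and chromosome 6 at 103599199.

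Across the lists, 3625 of the 5630 WT IRF4 summits (64.4%, 95% Wilson interval 63.1 to 65.6) had a p65KO summit within 200 bp. The same 3625 pairs made up 84.1% (83.0 to 85.1) of the 4312 p65KO summits. When the summits were shifted by 5 to 50 kb, a mean of 0.366% of WT and 0.478% of p65KO summits still met a partner. Summits with a partner scored higher. The WT median was 35.1 with a partner and 18.2 without (n = 3625 and 2005). In the p65KO list it was 30.7 against 17.5 (n = 3625 and 687). Both differences had p = 1e-05 in two-sided permutation tests, the smallest value these permutations can give, and 2e-05 after Benjamini-Hochberg adjustment over the 8 planned tests. Strong summits are called more easily in any second list, so this direction was likely beforehand.

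The matched share was higher at higher scores. In the highest decile of the WT list 99.5% (98.5 to 99.8) of 563 summits had a p65KO partner, in the fifth 69.8% (65.9 to 73.5) and in the lowest 28.2% (24.7 to 32.1). The highest p65KO decile had 99.8% (98.7 to 100) of 432 summits matched, and the lowest 59.9% (55.2 to 64.4). At the 3625 matched positions the scores of the 2 genotypes rose together, with Spearman's rho 0.746 and Pearson's r 0.881 (permutation p = 1e-05 for each, adjusted 1e-05 over 12 correlations). This correlation is across summits, which are not independent replicates. With both IRF4 lists reduced to the same length of 4312, 74.6% of each was matched.

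**Figure D2:**
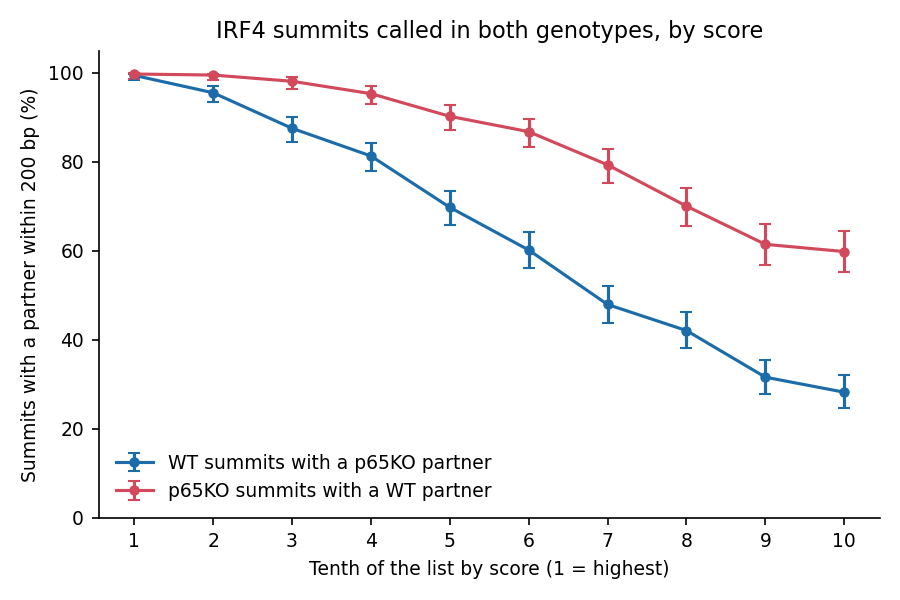
Percentage of IRF4 summits with a summit of the other genotype within 200 bp, by decile of the authors' score within each list, with bars for 95% Wilson intervals. The share falls from 99.5% to 28.2% in WT and from 99.8% to 59.9% in p65KO.

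Few strong sites belonged to 1 genotype. On placed chromosomes outside dense p65 regions, 1800 WT IRF4 summits had no p65KO summit within 1 kb, of 1895 in the whole list. The highest was chromosome 3 at 94183949, which scored 149 and ranked 76 in WT, with the nearest p65KO summit 573951 bp away. The next were chromosome 4 at 32406763 (75.8), chromosome 9 at 123782258 (73.2), chromosome 5 at 42055698 (67.9) and chromosome 9 at 88531872 (67.9). These 5 were chosen after their values were seen. In the other direction, 603 p65KO summits there had no WT summit within 1 kb, of 617 in the whole list, led by chromosome 1 at 137495189 with a score of 57.1. It was followed by chromosome 11 at 5906427 (47.9), chromosome 11 at 86152667 (45.8), chromosome 12 at 92020105 (44.2) and chromosome 3 at 130857695 (42.8). In the highest decile 3 of 563 WT and 1 of 432 p65KO summits lacked a partner within 200 bp.

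The second comparison asked whether RelA and IRF4 occupied the same sites in WT cells, which were stimulated differently for the 2 factors. Of the 797 p65 summits, 225 (28.2%, 25.2 to 31.5) lay within 200 bp of a WT IRF4 summit, against a mean of 0.878% after shifting. The share was 25.7% (21.2 to 30.9) among the 307 p65 summits outside unplaced sequence and dense regions, 29.9% (25 to 35.3) in dense regions and 29.7% (23.7 to 36.5) in unplaced sequence. The p65KO IRF4 list, from cells without RelA, met 179 p65 summits (22.5%, 19.7 to 25.5) against 0.424% after shifting, and 81 of the 307 (26.4%, 21.8 to 31.6). Both IRF4 lists had a summit at 138 p65 summits, and neither had one at 531.

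The strongest p65 positions were the most often shared. Each of the 20 highest p65 summits had an IRF4 summit within 200 bp in WT and in p65KO cells, as did 48 of the highest 50 and 88 of the highest 100. The p65 list was led by chr1_random at 272742, which scored 332 for p65, 268 for IRF4 in WT and 255 for IRF4 in p65KO cells. Next came chromosome 9 at 35112987 (p65 score 329), chromosome 16 at 11144209 (285), chromosome 3 at 5860624 (254) and chromosome 16 at 57391605 (243), which are also among the highest summits of both IRF4 lists. The rest of the p65 top 10 were chromosome 12 at 3109956, chromosome 15 at 74917261, chromosome X at 73844362, chromosome 6 at 103599194 and chromosome X at 109484536, with p65 scores from 204.7 to 224. By contrast 6 of the 10 highest WT IRF4 summits, 13 of the highest 50 and 14 of the highest 100 had a p65 summit. The p65 list is the shorter, and 225 of all 5630 WT IRF4 summits had a p65 summit.

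The median p65 score was 24.0 (13.5 to 45.2) at the 225 summits with a WT IRF4 partner and 7.77 (5.39 to 11.9) at the 572 without (two-sided permutation test, p = 1e-05, the smallest these permutations can give; adjusted 2e-05). Without unplaced sequence and dense regions the medians were 39.8 and 8.72, at 79 and 228 summits. Scores for p65 also rose with IRF4 scores at matched positions. On placed chromosomes outside dense regions, rho was 0.764 (95% bootstrap interval 0.610 to 0.869) and r 0.933 against WT IRF4 at 79 positions. Against IRF4 in RelA-deficient cells rho was 0.774 (0.618 to 0.886) and r 0.946 at 81 positions. All had permutation p = 1e-05 and adjusted 1e-05 over the 12 correlations. Without the 20 highest p65 summits the last rho was 0.610 (0.373 to 0.785) and r 0.678 at 67 positions. No input library and no p65 precipitation from RelA-deficient cells were analysed here.

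**Figure D3:**
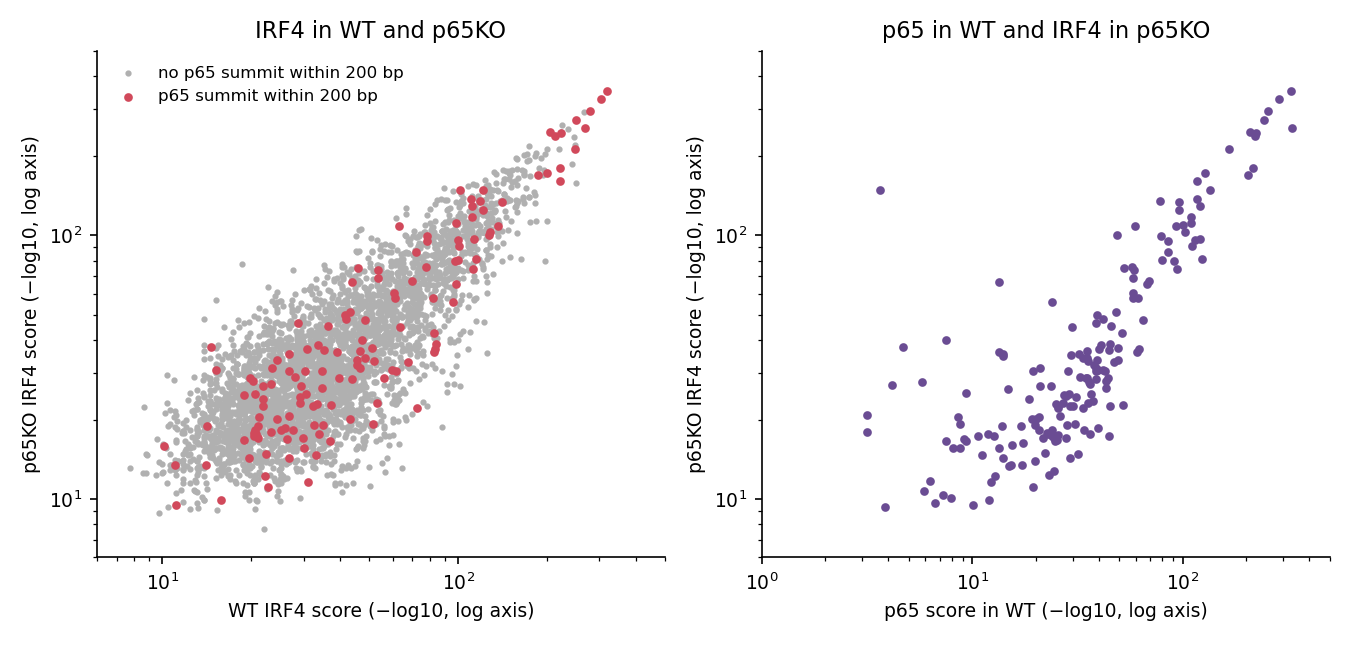
The authors' scores (−log10 scale, drawn on log axes) at summits matched within 200 bp between lists, 1 point per matched pair. The scores rise together for IRF4 in both genotypes (rho 0.746 over 3625 pairs) and for p65 in WT cells against IRF4 in p65KO cells.

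Outside unplaced sequence and dense regions, 198 p65 summits had no IRF4 summit of either genotype within 1 kb. The highest, chosen after their values were seen, were chromosome 3 at 135354535 (p65 score 40.8), chromosome 10 at 18735268 (33.4), chromosome 12 at 45817307 (28.2), chromosome 19 at 46379196 (27.3) and chromosome 12 at 56592964 (26.2). The nearest WT IRF4 summits were 2228 bp and 3454 bp away from the first and second of these. Conversely 3480 WT IRF4 summits had a p65KO partner and no p65 summit within 1 kb, among them chromosome 13 at 113077514 (score 249), chromosome 9 at 95052344 (249) and chromosome 18 at 65638959 (247).

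The third comparison was central to the design and asked whether WT IRF4 summits near a p65 summit were lost in RelA-deficient cells. Because p65 was mapped under another stimulation, RelA binding in the cells used for IRF4 was not measured. Signal that does not depend on the antibody would be matched with or without RelA. Of the 225 WT IRF4 summits with a p65 summit within 200 bp, 139 (61.8%) had a p65KO IRF4 summit. Of the 5405 without one, 3486 (64.5%) did. The odds ratio was 0.890 (0.671 to 1.19), and no difference was detected (two-sided Fisher's exact test, p = 0.435, adjusted 0.435). With p65 sought within 10 kb in place of 200 bp, a window chosen after the results were seen, it was 0.557 (0.442 to 0.702, exact test, p = 3.73e-07). It turned to 1.29 (0.86 to 1.96, exact test, p = 0.214) when unplaced sequence and dense p65 regions were also left out. With p65 within 200 bp, the odds ratio within deciles of the WT score was 0.664 (0.466 to 0.946, exact Cochran-Mantel-Haenszel test, two-sided, p = 0.0188, adjusted 0.0251), so that summits with p65 were matched less often than others of like score.

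WT IRF4 summits in unplaced sequence and dense p65 regions were matched less often than those elsewhere. Of 197 such summits, 73 (37.1%) had a p65KO partner, against 3552 of 5433 (65.4%) elsewhere (odds ratio within deciles 0.329, 0.228 to 0.472, exact test, p = 1.46e-10). Inside them, 69 of 137 summits with p65 (50.4%) and 4 of 60 without (6.67%) were matched, the opposite order (odds ratio within deciles 12.7, 4.04 to 53.5, exact test, p = 1.01e-07). Summits crowd together there, with 20 and 14 WT IRF4 summits in the dense regions of chromosome 5 that start at 14900181 and 15112862. Both exact tests treat such summits as independent. With unplaced sequence and dense regions left out of every list, 63 of 79 summits with p65 (79.7%) and 3488 of 5354 without (65.2%) were matched. The unstratified odds ratio was then 2.11 (1.20 to 3.92, Fisher's exact test, p = 0.006), and within deciles 0.845 (0.393 to 1.86, p = 0.713). The stratified call also ended when partners were sought within 500 bp (0.794) or 1 kb (1.01), above each list's median score (0.973), with IRF4 lists of equal length (0.701) and on autosomes alone (0.716). It held within 100 bp (0.467), with p65 within 10 kb (0.441), with 4 or 20 strata (0.654 and 0.656) and with 1 summit per region (0.683). With p65 within 10 kb and unplaced sequence and dense regions left out, the call was lost (0.717, 0.419 to 1.23, exact test, p = 0.240).

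The 139 IRF4 summits that had p65 and were matched in p65KO cells included chromosome 9 at 35112991, chromosome 16 at 11144200, chromosome 3 at 5860628, chr1_random at 272714, chromosome 16 at 57391617 and chromosome 5 at 147072755. Next in score were chromosome 12 at 3109929, chromosome X at 73844275, chromosome 11 at 108873155 and chromosome 15 at 74917265. There were 74 with p65 and no p65KO summit within 1 kb. Of the 10 highest of these, 6 were on unplaced contigs, led by chr4_random at 143097 (IRF4 score 71.8, p65 score 10.7) and chrUn_random at 5263059 (57.5 and 5.76), and chromosome 10 at 57686774 was in a dense region. Outside these regions lay chromosome 12 at 75905244 (51.1 and 10.7), chromosome 8 at 24206056 (51 and 5.21) and chromosome 19 at 23431964 (36.1 and 14.8). They were the highest of 15 such summits.

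A further comparison asked whether IRF4 summits of 1 genotype alone lay at p65 sites. A p65 summit was within 200 bp of 86 of 2005 WT summits without a p65KO partner (4.29%) and of 41 of 687 p65KO summits without a WT partner (5.97%). The odds ratio was 0.706 (0.476 to 1.06, two-sided Fisher's exact test, p = 0.0768, adjusted 0.0877), and no difference was detected. It passed the threshold with matching within 100 bp (0.595, exact test, p = 0.00717) and with 1 summit per region (0.670, exact test, p = 0.0461). Without unplaced sequence and dense regions the WT share was the lower, 16 of 1882 (0.850%) against 18 of 661 (2.72%). The odds ratio was 0.307 (0.145 to 0.641, exact test, p = 0.00111). Within 4 strata cut from the scores of both lists together it was 0.276 (exact Cochran-Mantel-Haenszel test, p = 0.00033). That test matched the full IRF4 lists and covered 16 of 1881 and 18 of 659 summits. With read depth unknown, scores of the 2 lists may not share a scale. With IRF4 lists of equal length the odds ratio was 1.09 (0.715 to 1.65, exact test, p = 0.761). The 17 p65KO summits with p65 and no WT summit within 1 kb outside these regions included chromosome X at 163645272 (IRF4 score 35.3, p65 score 14.1), chromosome 14 at 8465697 (35.0 and 14.1) and chromosome 14 at 112768251 (27.8 and 35.9).

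The last comparison concerned clusters, groups of at least 3 WT IRF4 summits joined at the distance customary for stitching super-enhancers, which lies between the alternatives of 5 and 25 kb. There were 151, covering 2245 kb, and they held 550 WT IRF4 summits (9.77%). Because WT summits define the clusters, the WT share in them is raised by construction. The clusters held 257 p65KO summits (5.96%, against 2.5% after shifting) and 139 p65 summits (17.4%, against 7.97%). Without unplaced sequence and dense regions, 4 of 307 p65 summits (1.30%, against 0.204%) lay in clusters. The clusters with most WT summits lay in dense p65 regions or unplaced sequence. Chromosome 5 from 14933870 to 15006864 had 13 WT IRF4, 5 p65KO IRF4 and 20 p65 summits, and chromosome 9 from 3000459 to 3038151 had 12, 9 and 14. Chromosome 5 from 15177147 to 15199454 had 9, 2 and 5. The others were on chrUn_random, from 3549584 to 3581030 (9, 5 and 7) and from 5317847 to 5341681 (9, 2 and 7).

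Of the 572 p65 summits without a WT IRF4 partner, 52 (9.09%) lay inside a cluster, against 17 (2.97%) after a shift of 50 kb (odds ratio 3.26, 1.83 to 6.10, two-sided Fisher's exact test, p = 1.66e-05, adjusted 2.66e-05). Outside unplaced sequence and dense regions 2 of 228 did and 0 of 228 after the shift, and the call was lost (Fisher's exact test, p = 0.499, the smallest p that 2 such summits allow). With clusters joined at 5 kb the odds ratio was 2.69 (0.641 to 15.8, exact test, p = 0.224). In each of these tests both groups are the same p65 summits, before and after the shift, and p65 summits crowd together. Fisher's test treats them as independent, so the p-values and intervals do not allow for the pairing or the crowding.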

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

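Leaving out unplaced sequence and dense p65 regions, widening the p65 window to 10 kb and shifting upstream were chosen only after the results were seen. No paired analysis was possible because each list pools its replicates and holds no values per replicate, although the groups share replicate numbers 1 and 2; leaving out a replicate was not possible for the same reason. The planned motif, genomic location and gene list alternatives were not run. The score differences (p = 1e-05) and the IRF4 rank correlation (rho 0.744 to 0.747) kept direction and call under every alternative run for them; the p65 score difference, 16.2, was 31.1 without unplaced sequence and dense regions. Read depth, unknown here, limits all list comparisons. The WT share matched in p65KO was 62.7% at 100 bp, 66.3% at 1 kb and 74.6% at equal length, and the reverse share 81.9%, 85.2% (500 bp), 85.7% (1 kb) and 74.6%. The p65 share matched to WT IRF4 was 22.8% at 100 bp, 35.1% at 1 kb and 23.1% at equal length; to p65KO IRF4, 18.8%, 27.0% (1 kb) and 26.4% without unplaced sequence and dense regions. The unstratified retention odds ratio turned to 1.01 at 1 kb, 1.44 above the median scores, 2.11 without those regions and 1.29 with p65 within 10 kb and without them; it was 0.557 (exact p = 3.73e-07) with p65 within 10 kb alone. Within score strata it was 0.794 at 500 bp, 1.01 at 1 kb, 0.973 above the medians, 0.701 at equal length, 0.716 on autosomes, 0.845 without those regions and 0.717 with p65 within 10 kb and without them, none past the threshold (p from 0.071 to 1). It held at 100 bp (0.467), with 4 or 20 strata (0.654 and 0.656), 1 summit per region (0.683) and p65 within 10 kb (0.441). The odds ratio for p65 at summits of 1 genotype passed the threshold at 100 bp (0.595, exact p = 0.00717), with 1 summit per region (0.670, p = 0.0461), without those regions (0.307, p = 0.00111; 0.425, p = 0.00136 with p65 within 10 kb), and turned to 1.09 at equal length. Clusters numbered 35 at 5 kb and 295 at 25 kb, by construction; the odds ratio for p65 inside them lost its call at 5 kb (2.69, exact p = 0.224) and had no finite value without those regions. Apart from window, length and construction, the cause of these changes was not tested.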

Other observations

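The tests of shared signal, of leaving out unplaced sequence and dense p65 regions, of retention inside and outside them and of the highest deciles, with and without p65, were chosen only after the lists and the results above had been seen.

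With unplaced sequence and dense p65 regions left out, 122 clusters of WT IRF4 summits held 4 of 307 p65 summits (1.30%, against 0.204% after shifting). The 5 with most WT summits, chosen after their values were seen, held none of them. Chromosome 5 from 53786017 to 53821568 had 8 WT and 6 p65KO IRF4 summits, with a highest WT score of 219.9 at position 53793421. Chromosome 1 from 60932400 to 60970379 had 7 and 5. Chromosome 12 had a cluster from 74980918 to 75014444 with 5 and 3 and one from 109872269 to 109885091 with 5 and 1. On chromosome 2 the cluster from 128193668 to 128227304 had 5 and 3.

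Each of the 20 highest p65 summits had an IRF4 summit within 200 bp in both genotypes, while 11 of the 20 highest WT IRF4 summits had a p65 summit. The lists differ in length, 797 p65 against 5630 WT IRF4 summits, which limits this contrast. Unplaced sequence and dense p65 regions as the whole cause are argued against, since 25.7% of p65 summits had a WT IRF4 partner once these were left out; repeats elsewhere were not tested. Signal that does not depend on the antibody, such as sequence that attracts reads in any precipitation called without input, is a candidate explanation: outside these regions p65 scores and IRF4 scores from RelA-deficient cells rose together (rho 0.774, and 0.610 without the 20 highest p65 summits). Sites that both factors bind, with IRF4 bound there without RelA, could give the same correlation and stay open as untested. An input library or a p65 precipitation from RelA-deficient cells, not analysed here, would part the explanations.

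At a given score, WT IRF4 summits with p65 were matched less often in p65KO cells, an odds ratio of 0.664 (0.466 to 0.946). This call held under some alternatives and was lost under others, as given above. Of the 225 summits with p65, 137 lay in unplaced sequence and dense p65 regions, against 60 of the 5405 without. Fewer summits were matched there than elsewhere (37.1% against 65.4%). The pooled 0.664 was below the odds ratio inside these regions (12.7) and that with them left out (0.845). The interval of the latter (0.393 to 1.86) includes it. Whether the lower match rate there is the whole cause could not be decided. For summits with p65 the odds ratio inside against outside was 0.516 within deciles (0.221 to 1.17, exact test, p = 0.0904). For summits without p65 it was 0.0353 (0.00748 to 0.115, exact test, p = 2.9e-15), and inside these regions summits with p65 were matched more often than those without (69 of 137 against 4 of 60, odds ratio 12.7). Read depth, differences between animals and signal that does not depend on the antibody stay open, and these tests treat crowded summits as independent. A need of IRF4 for RelA at shared sites cannot be told apart from no effect outside these regions, where the odds ratio was 0.845 with an interval from 0.393 to 1.86, because 79 WT summits there had p65.

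The share of WT IRF4 summits without a p65KO partner fell with the score. A general loss of IRF4 calls at strong sites without RelA is argued against, since 0.53% of the highest WT decile lacked a partner. These were 3 of 563 summits, all 3 among the 521 without p65 within 200 bp. A general weakening of strong sites is not addressed, since this decile began at a score of 74.3 and p65KO summits were called down to 7.5. Signal that does not depend on the antibody, left open above, would be matched without IRF4 binding. Whether a few strong sites were lost stays open: the odds ratio of lacking a partner in the highest decile, WT against p65KO, was 2.31 (0.185 to 121, exact test, p = 0.637), on 3 and 1 summits. Less sensitive calling in the p65KO list, from fewer samples or lower read depth, could give the WT decline, as could a weakening of low-scoring sites in p65KO cells. Neither was tested. The p65KO list showed a like decline, with no WT partner for 173 of 431 summits in its lowest decile and 1 of 432 in its highest. Neither explanation would by itself give the p65KO decline, whose cause was not tested.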
